A study of Mus musculus with 23 samples.

How the data were processed

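The series measured 2 histone marks, H3K27ac (acetylation of lysine 27 of histone H3, found at active enhancers and promoters) and H3K4me2 (dimethylation of lysine 4, found at enhancers and promoters whether or not they are active), by chromatin immunoprecipitation and sequencing. Per the labels, the tissue came from C57BL6J mice at postnatal day 56, and covered 4 cortical subregions: anterior cingulate cortex (ACC), retrosplenial cortex (RSC), lateral entorhinal cortex (LEC) and medial entorhinal cortex (MEC). Per the labels' protocols, brains were cut into horizontal or coronal sections of 500 µm, the subregions were dissected from both hemispheres of unstained tissue by their architecture, and the tissue was snap-frozen before chromatin was prepared. The labels describe 23 samples: 2 libraries for each subregion and mark, except MEC H3K4me2 with 1, and 2 input libraries per subregion. The sex of the animals, and whether libraries of a group came from separate animals, are not given in the sources used here.

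Per the submitters' processing notes, the tools included Bowtie 1.1.1 and bedtools 2.19.0, and the genome build was mm9. The peak caller, its threshold and the way replicates were combined are not given in the sources used here. The deposited lists are named as reproducible enriched regions, and each subregion and mark has 2 of them, a full list and an enhancer list. Every region of an enhancer list was also in the full list of its subregion and mark, tested on the lists. The rule that removed the other regions is not given in the sources used here, so these are called excluded regions and not promoters. The deposited score values were the width of each region in bp in every list that had them (0 exceptions), so they gave no enrichment. The 2 MEC H3K27ac lists had 3 columns and no score. Positions lay on a grid of 25 bp, and the narrowest region was 500 bp in the MEC lists and 525 bp in all others. A further deposited list repeated the MEC H3K27ac enhancer list byte for byte and was not used, which left 16 of 17. No input list, signal or read count was analysed here, so the sequencing depth behind each list is unknown. A longer list may therefore hold more enhancers or come from deeper libraries. The lists give no values per library, so there is no spread between animals, and no test across animals could be made.

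All values were computed from the lists with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Enhancer lists of a mark were merged into elements wherever regions overlapped by at least 1 bp, and each element was classed by the subregions that contributed to it. An element was unique to a subregion when no other subregion contributed. A unique H3K27ac element was called doubly marked when it overlapped an H3K4me2 enhancer region of its own subregion and of no other. Pairs of lists were compared by the bases in both lists as a percentage of the bases in either (the Jaccard index) and by the percentage of regions overlapped. For the chance level of an overlap, a list was shifted around each chromosome by a random distance 100 times. Ranges in brackets after percentages are Wilson 95% intervals, which cover counting error only and carry nothing about variation between animals. Elements are not replicates of a subregion, and neighbouring elements are not independent, so the p-values describe these lists and not the animals.

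Dependence of uniqueness between the marks was tested per subregion with a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over 4 tests. Uniqueness of enhancer against excluded regions was tested in the same way over 8 tests, with regions called unique when they overlapped no region in the full lists of the other subregions. Clustering of unique H3K27ac elements was tested with a one-sided permutation test: the number with another unique element of that subregion within 100 kb, between midpoints, was set against 10000 random draws of as many elements from all H3K27ac elements of the subregion. It was adjusted over 4 tests. Overlap of MEC regions by RSC was set against overlap by LEC and by ACC over the same MEC regions with a two-sided exact binomial test, adjusted over 4 tests and chosen after the data were seen. On simulated lists, the merging step recovered 8000 of 8000 planted elements and 3004 of 3004 unique ones. On the real lists it gave as many elements as bedtools 2.31.1. With elements drawn from the LEC H3K27ac list, the cluster test gave p under 0.05 for 1 of 40 random sets and 40 of 40 sets built from neighbouring regions.

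The groups, the main tests, the other settings to try and the rule for named regions were fixed before the data were examined. The rule named, per subregion, the 3 clusters with the most unique H3K27ac elements (chained at gaps up to 100 kb) and the 2 widest doubly marked elements. Coordinates are 1-based and in mm9. The gene table at hand is for GRCm38.p6, another build: the last region on chromosome 1 ended at 197068900, beyond its last gene end of 195291439. Coordinates were not converted between builds, so no gene is named and the planned test of 17 gene lists was not run. Alternatives covered the overlap that counts as shared (50% of the shorter region), merging within 1000 bp, unmerged regions, lists cut or thinned to one length, the widest regions only, full lists, 3 subregions without MEC, width windows and cluster distances of 20 and 500 kb.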

Results

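Enriched regions of H3K27ac and H3K4me2 were listed for 4 subregions of the adult mouse cortex, to find how active enhancers differ between closely related parts of the cortex and so could drive subregion-specific expression. ACC and RSC are midline cortical areas, and LEC and MEC are the lateral and medial divisions of the entorhinal cortex, the main gateway between neocortex and hippocampus. Each subregion and mark had a full and an enhancer list with no values per library, so the values have no replicate error and the depth behind them is unknown.

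ACC had the longest enhancer lists and MEC the shortest for both marks. The ACC H3K27ac enhancer list held 27909 regions covering 81.6 Mb, against 24272 (69.1 Mb) in RSC, 22973 (67.8 Mb) in LEC and 10951 (29.98 Mb) in MEC. For H3K4me2 the numbers were 34180 regions (72.1 Mb) in ACC, 28675 (54.1 Mb) in RSC, 29125 (57.7 Mb) in LEC and 15041 (14.5 Mb) in MEC. H3K27ac enhancer regions had similar median widths in all 4 subregions, from 2075 bp in ACC and RSC to 2200 bp in LEC. MEC H3K4me2 enhancer regions were narrower, with a median of 750 bp against 1500 to 1600 bp elsewhere.

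The full lists kept the order of the extremes: ACC had 48266 H3K27ac and 54419 H3K4me2 regions, and MEC had 22848 and 30064. RSC had 41584 and 46552, and LEC had 42136 and 48182. Enhancer regions made up 57.8% (57.4 to 58.3) of the full H3K27ac list in ACC, 58.4% (57.9 to 58.8) in RSC and 54.5% (54.0 to 55.0) in LEC, but 47.9% (47.3 to 48.6) in MEC. Since libraries cannot be compared in depth, the differences in list length cannot be assigned to the tissue.

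**Figure D1:**
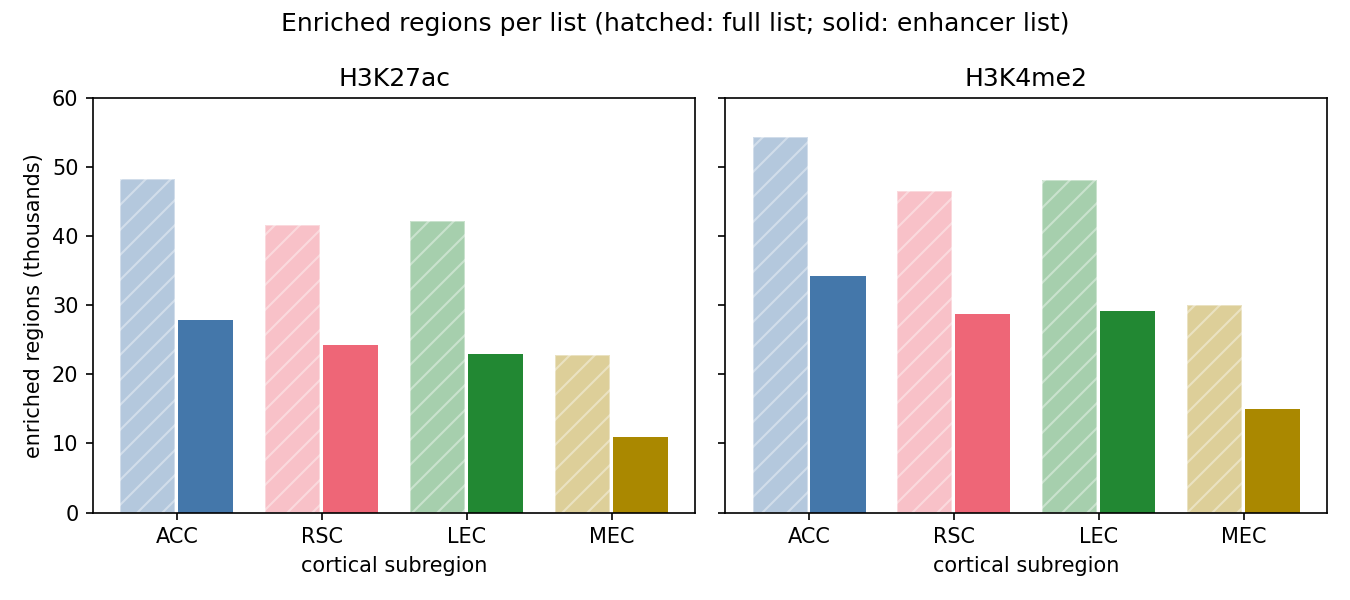
Number of enriched regions (vertical axis, in units of 1000) per cortical subregion for H3K27ac and H3K4me2, with full lists hatched and enhancer lists solid. ACC was highest and MEC lowest in each kind of list, with 27909 and 10951 H3K27ac enhancer regions.

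The first comparison asked which enhancers were carried by a single subregion and which were common to all 4. In the enhancer lists, most elements were carried by 1 or 2 subregions. Of 42115 merged H3K27ac elements, 43.2% (42.7 to 43.7) came from 1 subregion, 27.2% (26.7 to 27.6) from 2, 19.9% (19.6 to 20.3) from 3 and 9.72% (9.44 to 10.003) from all 4. H3K4me2 gave nearly the same division: of 52088 elements, 41.0% (40.6 to 41.4) came from 1 subregion and 9.91% (9.65 to 10.2) from all 4. These shares depended on the setting: for H3K27ac, the full lists gave 30.3% in 1 subregion and 19.7% in all 4, unmerged regions 21.1% and 19.7%, and lists thinned at random 65.5% and 1.44%.

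ACC had 6395 unique H3K27ac elements, RSC 4958, LEC 4646 and MEC 2186. As a share of the elements of each subregion this was 23.6% (23.1 to 24.2) in ACC, above RSC at 21.3% (20.7 to 21.8), LEC at 21.1% (20.6 to 21.7) and MEC at 21.3% (20.5 to 22.1), whose intervals overlapped. MEC was lowest when full-list H3K27ac regions elsewhere were counted, over regions before merging. By this count 10.1% (9.50 to 10.6) of enhancer regions were unique in MEC, 16.4% in RSC, 16.5% in LEC and 21.01% in ACC. For H3K4me2 the highest share in the enhancer lists was in MEC, where 4904 elements or 33.6% (32.9 to 34.4) were unique. It was 20.97% (20.5 to 21.4) in ACC with 7102, 16.5% (16.1 to 16.9) in RSC with 4620 and 16.6% (16.2 to 17.02) in LEC with 4727. The MEC lead over ACC was nearly gone when regions left out of the enhancer lists elsewhere were counted, over regions before merging. By this count 20.2% (19.6 to 20.9) of MEC and 19.99% (19.6 to 20.4) of ACC H3K4me2 enhancer regions overlapped no full-list H3K4me2 region elsewhere. MEC stayed above RSC at 13.6% (13.3 to 14.1) and LEC at 14.3% (13.9 to 14.7). The labels describe 1 library for MEC H3K4me2, and 72.4% of its enhancer regions were under 1000 bp, against 11.1% to 13.0% elsewhere. Against the other enhancer lists, 47.1% of its regions of 500 to 575 bp were unique, and 18.1% of those of at least 1075 bp. The high MEC share therefore cannot be assigned to the tissue. The commonest shared class was ACC, RSC and LEC without MEC, with 5901 H3K27ac and 8827 H3K4me2 elements. Among H3K27ac elements in MEC and 1 other subregion, 748 were with RSC, 403 with LEC and 329 with ACC.

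Unique elements were narrower than shared ones. Median H3K27ac widths were 1225 against 3050 bp in ACC and 1325 against 3225 bp in RSC. They were 1550 against 3250 bp in LEC and 1700 against 4275 bp in MEC. A shared element joins overlapping regions of different lists, so part of this difference is built in. Before merging, narrow regions were still unique more often. In ACC 48.4% of H3K27ac regions of 525 to 1300 bp were unique, against 4.87% of those of at least 3475 bp. In MEC it was 29.3% for 500 to 1350 bp and 13.0% for at least 3275 bp. Some unique elements were in an excluded region of another subregion. The full H3K27ac lists elsewhere overlapped 8.29% (7.64 to 8.99) of ACC-unique elements, 19.7% (18.6 to 20.8) of RSC-unique, 18.4% (17.3 to 19.5) of LEC-unique and 49.6% (47.5 to 51.7) of MEC-unique elements. The full H3K4me2 lists elsewhere overlapped 3.82% (3.39 to 4.29) of ACC-unique, 15.3% (14.3 to 16.3) of RSC-unique, 11.7% (10.8 to 12.6) of LEC-unique and 37.9% (36.6 to 39.3) of MEC-unique H3K4me2 elements. Absent from the full lists of both marks in every other subregion were 3292 ACC-unique, 2920 RSC-unique, 2203 LEC-unique and 894 MEC-unique H3K27ac elements.

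MEC also had the fewest unique H3K27ac elements among the widest 50% of each list (1175 against 3355 in ACC, 2488 in RSC and 2420 in LEC) and in the full lists (1262). With lists brought to the MEC length, which changes uniqueness by construction, it was highest when the widest regions were kept (3994 against 2058, 2095 and 2432) and level when lists were thinned at random (4704 against 5030, 4719 and 4923).

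**Figure D2:**
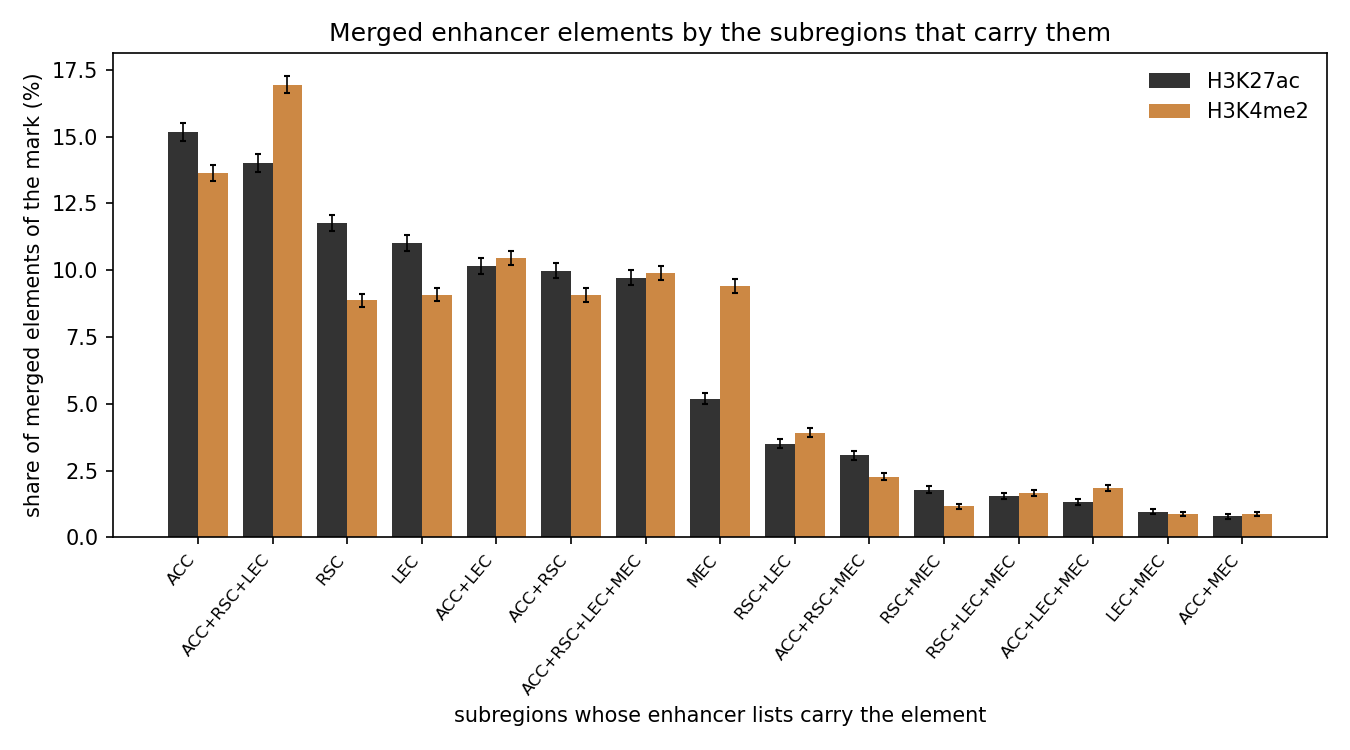
Share of merged enhancer elements of each mark (percent, vertical axis) carried by each combination of subregions, with Wilson 95% intervals as error bars (counting error only). ACC alone and the trio of ACC, RSC and LEC led for H3K27ac, with 15.2% and 14.0%, and the trio led for H3K4me2 with 16.9%.

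The next comparison asked which subregions resembled each other most. ACC shared most with RSC and LEC, and RSC and LEC shared less with each other. For H3K27ac, ACC and RSC shared 42.6% of their bases, ACC and LEC 41.2%, and RSC and LEC 35.0%. MEC shared 23.5% with RSC, 19.3% with LEC and 18.0% with ACC. The order was close to this for H3K4me2, where ACC shared 44.7% with LEC and 43.2% with RSC, RSC and LEC shared 39.7%, and MEC shared 13.6% with RSC, 12.3% with LEC and 10.3% with ACC.

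MEC resembled RSC more than it resembled LEC, the other entorhinal division, in H3K27ac. The RSC list overlapped 67.0% (66.1 to 67.9) of the MEC H3K27ac enhancer regions, the longer ACC list 61.9% (61.0 to 62.9) and the LEC list 56.2% (55.3 to 57.2), where shifted lists gave 4.97%, 5.83% and 4.81%. Over the MEC regions, 2253 were overlapped by RSC and not LEC and 1072 by LEC and not RSC (two-sided exact binomial test, p = 4.4e-95, adjusted p = 1.8e-94 over 4 tests). Against ACC the numbers were 1533 and 978 (p = 1.2e-28, adjusted p = 2.5e-28, same exact test). In H3K4me2 the RSC lead was smaller: 1936 regions against 1546 for LEC (p = 4.1e-11, adjusted p = 5.5e-11) and 1562 against 1536 for ACC (p = 0.653, adjusted p = 0.653), by the same exact test. The H3K4me2 lists differed in length, with 28675 regions in RSC, 29125 in LEC and 34180 in ACC, which the test does not correct for.

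The percentage of bases shared is bounded by the length of the shorter list, so the low MEC values partly measure its shorter lists. By the share of the shorter list overlapped, MEC with RSC (67.0%) was level with ACC and RSC (67.0%) and above RSC and LEC (55.5%) in H3K27ac, whereas in H3K4me2 the MEC pairs stayed lowest, at 51.1% to 53.7% against 60.3% to 72.0%.

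**Figure D3:**
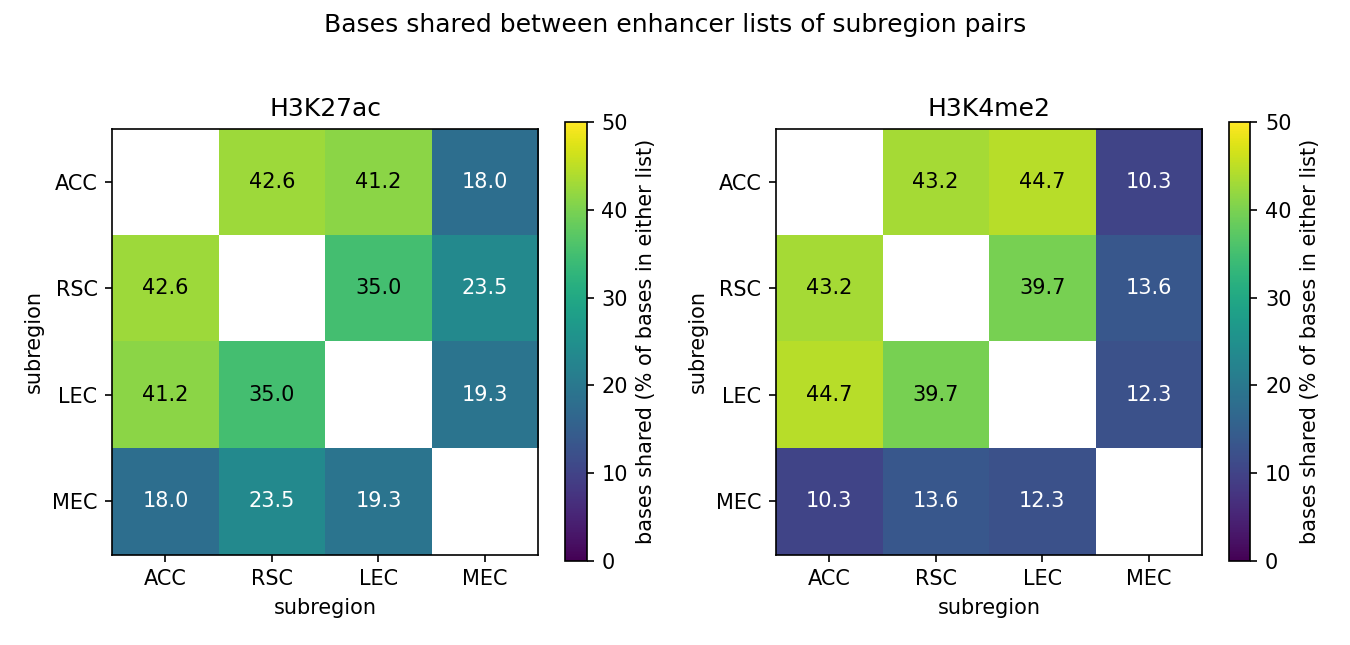
Bases shared between the enhancer lists of each pair of subregions (colour and printed number, percent of the bases in either list) for H3K27ac and H3K4me2. ACC, RSC and LEC shared 35.0% to 44.7% with each other, and MEC shared most with RSC, 23.5% and 13.6%.

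A further comparison asked whether enhancers carried both marks and whether uniqueness in H3K27ac went with uniqueness in H3K4me2. Most H3K27ac enhancer regions carried H3K4me2 in ACC, at 61.0% (60.4 to 61.6), LEC, at 60.5% (59.8 to 61.1), and RSC, at 53.7% (53.0 to 54.3). In MEC it was 34.3% (33.4 to 35.2). Shifted lists gave 6.22% in ACC, 5.19% in LEC, 4.998% in RSC and 2.07% in MEC. In the full lists MEC came close to the others, with 62.2% against 69.1% in ACC, 64.5% in RSC and 70.3% in LEC.

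H3K27ac elements unique to ACC, RSC or LEC carried H3K4me2 of their own subregion more often than that of any other. ACC-unique elements overlapped ACC H3K4me2 regions in 44.7% (43.5 to 45.9) of cases, LEC ones in 28.7% (27.6 to 29.8), RSC ones in 27.6% (26.5 to 28.7) and MEC ones in 8.80% (8.13 to 9.52). LEC-unique elements overlapped LEC H3K4me2 regions in 42.8% (41.4 to 44.2) and the longer ACC list in 33.5% (32.2 to 34.9). RSC-unique elements overlapped RSC H3K4me2 regions in 27.7% (26.5 to 29.0) and ACC regions in 21.6% (20.5 to 22.8). MEC-unique elements did not show this: the MEC list overlapped 20.5% (18.9 to 22.3) of them and the RSC list 24.1% (22.3 to 25.9). The MEC H3K4me2 list was much shorter, with 15041 regions covering 14.5 Mb against 28675 covering 54.1 Mb in RSC. Its length alone could lower the overlap, so MEC cannot be called an exception.

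Doubly marked elements, unique in H3K27ac and carrying H3K4me2 of their own subregion alone, numbered 847 in ACC, 639 in LEC, 481 in RSC and 218 in MEC. They were 13.2% (12.4 to 14.1) of unique H3K27ac elements in ACC, 13.8% (12.8 to 14.8) in LEC, 9.70% (8.91 to 10.6) in RSC and 9.97% (8.79 to 11.3) in MEC. Without elements that overlapped any full-list region of either mark elsewhere, there were 789 in ACC, 554 in LEC, 380 in RSC and 69 in MEC. With lists brought to the MEC length, which changes uniqueness by construction, MEC was no longer lowest. Keeping the widest regions gave 312 in ACC, 312 in LEC, 200 in RSC and 400 in MEC. Thinning at random gave 505, 545, 428 and 503 in the same order.

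Uniqueness of the marks went together in all 4 subregions. Among H3K27ac elements carrying H3K4me2 of their own subregion, H3K4me2 was unique in 29.6% (28.0 to 31.3) of ACC-unique elements and 9.85% (9.36 to 10.4) of those ACC shared, an odds ratio of 3.86. The odds ratio was 6.04 in RSC, 8.88 in LEC and 19.1 in MEC, where H3K4me2 was unique in 48.6% (44.0 to 53.2) of unique and 4.72% (4.05 to 5.49) of shared elements. Of the doubly marked elements behind these values, 69 of 218 in MEC and 789 of 847 in ACC were absent from the full lists of both marks elsewhere. In the full lists, a setting chosen after the data were seen, the odds ratios were 5.48 in ACC, 10.9 in RSC, 14.4 in LEC and 76.5 in MEC. The MEC value came with 90 doubly marked elements, against 1065 in ACC. Shared elements were wider, in part because they join regions of different lists, which makes overlap with H3K4me2 regions of other subregions easier. Among elements of 1000 to 3000 bp, also chosen after the data were seen, the odds ratios were lower. They were 2.60 in ACC, 4.21 in RSC, 6.07 in LEC and 17.0 in MEC. In the main setting the largest of the 4 adjusted p-values was 6.4e-123 by the two-sided Fisher exact test. Elements are not replicates, and the direction was the same in 4 of 4 subregions.

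**Figure D4:**
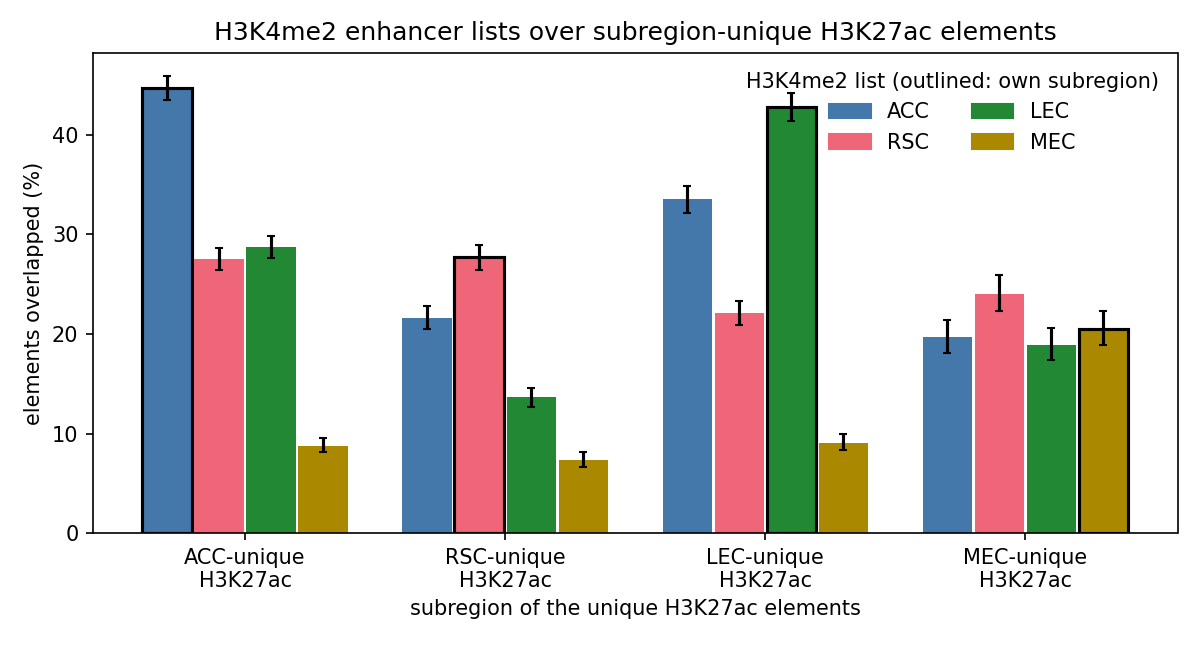
Percentage of subregion-unique H3K27ac elements (vertical axis, by subregion) overlapped by the H3K4me2 enhancer list of each subregion (colour, own subregion outlined), with Wilson 95% intervals for counting error. The own list was highest in ACC (44.7%), RSC (27.7%) and LEC (42.8%), and in MEC the RSC list was highest (24.1% against 20.5%). The MEC H3K4me2 list was the shortest.

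Enhancer regions were then set against the regions excluded from the enhancer lists. Enhancer regions were unique to their subregion more often than excluded ones in all 4 subregions and both marks. For H3K27ac, 21.01% (20.5 to 21.5) of ACC enhancer regions and 10.2% (9.79 to 10.6) of ACC excluded regions overlapped no full-list region elsewhere. It was 16.4% (15.9 to 16.9) against 3.77% (3.498 to 4.07) in RSC, 16.5% (16.04 to 16.996) against 5.47% (5.16 to 5.81) in LEC and 10.1% (9.50 to 10.6) against 1.35% (1.16 to 1.58) in MEC. Odds ratios were 2.34 in ACC, 5.01 in RSC, 3.41 in LEC and 8.15 in MEC. For H3K4me2 they were 3.05, 4.62, 3.41 and 15.4 in the same order, and the largest of the 8 adjusted p-values was 6.3e-200 (two-sided Fisher exact test).

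Among regions of 500 to 2000 bp all 8 odds ratios were lower. For H3K27ac the odds ratio was 1.36 in ACC, 3.12 in RSC, 2.00 in LEC and 8.01 in MEC, and for H3K4me2 it was 1.12 in ACC, 1.59 in RSC, 1.11 in LEC and 6.49 in MEC, with a largest adjusted p of 0.0141 by the same exact test.

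The last comparison asked whether unique H3K27ac elements lay near each other along the genome. Within 100 kb they did so beyond the background of their list in MEC, and ACC, RSC and LEC did not pass the test. The difference between subregions was not tested, and the calls changed with the distance. Of the MEC-unique elements, 49.6% overlapped full-list H3K27ac regions elsewhere, and the test was not repeated without them. In MEC 940 of 2186 unique elements had another within 100 kb, against 831 ± 27.5 (SD over 10000 draws) in random draws, a ratio of 1.13 (one-sided permutation p = 0.0001, the smallest these draws can give, adjusted p = 0.0004). The ratio was 0.990 in ACC, 0.992 in RSC and 0.991 in LEC (permutation adjusted p = 0.841 in each). Within 20 kb RSC (ratio 1.15, permutation adjusted p = 0.000267) and LEC (1.20, permutation adjusted p = 0.0002) passed the test as MEC did (1.996, permutation adjusted p = 0.0002), and ACC did not (0.9998, permutation adjusted p = 0.504). Within 500 kb MEC no longer passed (0.9997, permutation adjusted p = 0.974). Among doubly marked elements within 100 kb, ACC (1.28, permutation adjusted p = 0.0220) and MEC (2.37, permutation adjusted p = 0.0104) passed, and LEC (1.27, permutation adjusted p = 0.0615) and RSC (0.946, permutation adjusted p = 0.617) did not. With autosomes alone, a setting chosen after the data were seen, ACC still passed (1.29, permutation adjusted p = 0.0380) and MEC did not (1.69, permutation adjusted p = 0.119).

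The named clusters were picked for the most unique H3K27ac elements, so an H3K27ac lead of the own subregion in them is built in. Unique elements of ACC, RSC and LEC did not cluster beyond background within 100 kb (ratios 0.990, 0.992 and 0.991). Their clusters are therefore given as locations only. The largest LEC cluster, chr2:179202851-179531875, held 16 unique elements over 329 kb, 4 of them doubly marked. LEC had 23 H3K27ac enhancer regions there covering 64.6 kb, ACC had 8 covering 20.3 kb, RSC had 1 and MEC 0. H3K4me2 did not follow: ACC had 21 regions in the span and LEC 20, with 10 in RSC and 1 in MEC. The other LEC clusters were chr6:39858676-40164100 with 12 unique elements, where ACC and RSC also had 19 and 16 regions, and chr6:118627601-118841375 with 11. At the latter LEC had 21 H3K27ac enhancer regions, ACC 4, RSC 11 and MEC 0. The full H3K27ac lists had 24, 10, 14 and 0 there in this order.

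**Figure D5:**
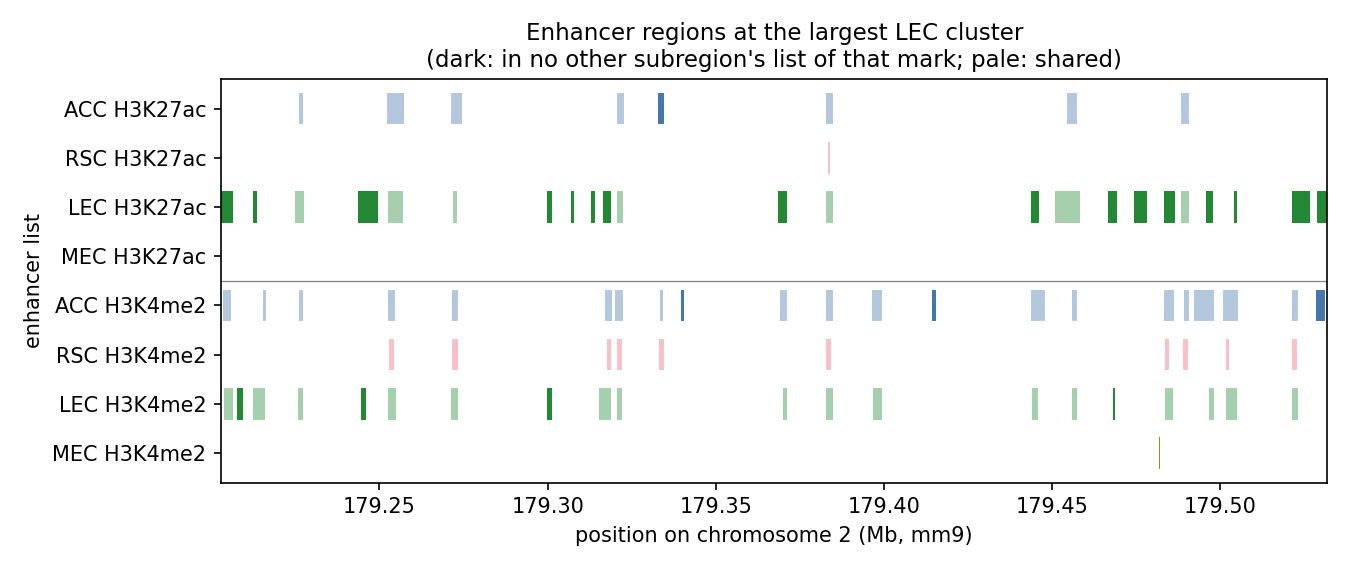
Enhancer regions of each subregion and mark (rows) along chromosome 2 (horizontal axis, Mb, mm9) across the LEC cluster, drawn dark where no other subregion's list of that mark overlapped and pale where shared. LEC had 23 H3K27ac regions against 8 in ACC, while H3K4me2 regions were about as many in ACC (21) as in LEC (20). The span was picked for its LEC-unique H3K27ac elements, so the H3K27ac lead is built in.

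The largest RSC cluster, chr2:169431926-169689125, held 16 unique elements. RSC had 25 H3K27ac regions there covering 82.9 kb, against 6 in ACC, 7 in LEC and 3 in MEC. H3K4me2 regions there numbered 14 in RSC, 12 in ACC, 16 in LEC and 6 in MEC. At chr17:62948051-63168925 RSC had 14 H3K27ac regions, 12 of its elements being unique, where ACC had 2, LEC 1 and MEC 0. H3K4me2 also led in RSC at this site, with 7 regions against 4 in ACC, 4 in LEC and 3 in MEC. The third, chr1:177068551-177400475, held 11 unique elements among 21 RSC regions, with 13 regions in ACC. The largest ACC cluster, chr13:52506676-52786700, held 12 unique elements, none of them doubly marked. ACC had 21 regions there covering 53.7 kb and RSC 13 covering 42.35 kb, with 7 in LEC and 2 in MEC. The others were chr1:182999226-183379175 with 11 unique elements, where ACC had 16 regions, RSC 5, LEC 6 and MEC 1, and chr2:27545826-27787950 with 11. The full H3K27ac lists had 20 regions in ACC, 10 in RSC, 13 in LEC and 6 in MEC at the chromosome 1 site. At the chromosome 2 site ACC had 16 H3K27ac enhancer regions covering 29.0 kb, against 3 in RSC, 5 in LEC and 1 in MEC. The full lists had 19, 6, 8 and 2 there in this order. H3K4me2 went the same way in it, with 10 regions in ACC, 3 in RSC, 5 in LEC and 1 in MEC.

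The largest MEC cluster was on chromosome Y, chrY:2779176-2902500, with 10 unique elements, 9 of them doubly marked, and no H3K27ac region of any other subregion even in the full lists. The sex of the animals is not given, so this cluster cannot be set apart from a difference in the animals used. Every full H3K27ac list had some chromosome Y regions, 6 in ACC, 10 in RSC, 7 in LEC and 19 in MEC. Other causes, such as read mapping, were not tested. The others were chr12:101540351-101677950 and chr19:10305726-10509550 with 8 unique elements each. In the chromosome 19 cluster MEC had 11 H3K27ac enhancer regions, ACC 5, RSC 4 and LEC 6. The full H3K27ac lists had 14, 12, 8 and 11 there in this order. In the chromosome 12 cluster MEC had 9 H3K27ac enhancer regions against 1 in ACC, 0 in RSC and 1 in LEC, but the full H3K27ac lists had 6, 5 and 9 regions there in these subregions. H3K4me2 enhancer regions ran opposite, with 1 in MEC against 11 in ACC, 12 in RSC and 12 in LEC.

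The widest doubly marked elements of LEC were chr7:6810101-6824325 (14225 bp) and chr6:99374451-99383275 (8825 bp). Those of RSC were chr14:64393076-64399825 (6750 bp) and chr5:45582851-45589500 (6650 bp). None of these 4 overlapped a full-list region of either mark in another subregion, and the same held for chr15:74248576-74257100 (8525 bp) in ACC. The other ACC element, chr16:35175726-35187900 (12175 bp), overlapped LEC full-list regions of both marks. Both MEC elements, chr14:41760151-41774000 (13850 bp) and chr8:87252551-87262825 (10275 bp), overlapped full-list regions of other subregions.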

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

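The comparisons of list properties between subregions and the tests of differences between odds ratios were chosen after the results were seen. For each of 18 properties of the enhancer lists, the subregion farthest from the others was compared with the range of all 4 (Dixon's ratio at its 95% critical value). Subregions are not replicates of a group, and chance alone picks out about 1 in 20 such sets.

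MEC stood apart in 4 of the 6 properties picked out, all of them of its H3K4me2 enhancer list, for which the labels describe 1 library. Its median width was 750 bp against 1500 to 1600 bp, and 72.4% of its regions were under 1000 bp wide against 11.1% to 13.0%. Chromosome X held 4.46% of its regions against 2.05% to 2.21%, a value of 2.41% among regions of at least 1000 bp. Chromosome Y held 70 of its regions against 4 to 6 elsewhere, and 19 against 3 to 6 among regions of at least 1000 bp. It also held 2 mitochondrial regions, against 0 in the H3K4me2 enhancer lists of ACC, RSC and LEC, and the cause was not tested. In H3K27ac, LEC had the fewest regions under 1000 bp, 7.62% against 10.7% to 11.3%. ACC had the highest share of unique H3K27ac elements, 23.6% against 21.1% to 21.3%.

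The odds ratios differed between subregions by Woolf's chi-square test of homogeneity over elements, which are not replicates. The test assumes independent subregions, but shared elements count in each subregion that carries them, and uniqueness in one list depends on the others. Its p-values are therefore descriptive only. The coupling of uniqueness between the marks was 19.1 in MEC and 3.86 in ACC (chi-square p = 2.1e-43). Of the doubly marked elements behind these, 69 of 218 in MEC and 789 of 847 in ACC were absent from the full lists of both marks elsewhere. In the full lists the coupling was 76.5 in MEC and 5.48 in ACC (chi-square p = 1.7e-80), from 90 and 1065 doubly marked elements. Uniqueness of enhancer against excluded regions had an odds ratio of 8.15 in MEC and 2.34 in ACC for H3K27ac (chi-square p = 4.0e-77), and of 15.4 in MEC and 3.05 in ACC for H3K4me2 (chi-square p = 7.5e-109).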

How the results depend on the processing

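The autosome-only values, the width window and the full lists for coupling, the strict H3K4me2 and doubly marked counts and the equal-length MEC overlaps were chosen after seeing the data. No paired analysis was possible because the lists give no values per library, although the labels share replicate numbers. For the same reason no replicate could be left out, and the gene list analysis was not run for lack of mm9 gene positions. Of the alternative values of tests, 43 stayed on the same side of the threshold with no called change of direction, 5 reversed and 1 was weaker. The 43 include clustering ratios that crossed 1 with neither value past the threshold, ACC at 1.004 within 500 kb and LEC at 1.27 among doubly marked elements (1.30 on autosomes). All coupling odds ratios (2.60 to 76.5) and all ratios for enhancer against excluded regions (1.11 to 8.01) stayed above 1 and past the threshold. Of the alternative counts, 81 were within 1.5 times the main count and 36 were not. Of the alternative shares, 20 were within the counting interval of the main value, which is narrow at these numbers, and 94 were not. The alternatives include unlike measures, such as the share of regions of the shorter list overlapped against a share of bases. Others change the shares by construction, so this tally does not measure robustness. Unknown depth limits every count, since a missing region cannot be told from one missed at low depth. Requiring 50% overlap moved no count beyond 1.5 times. Except where the construction is named, the cause was not tested.

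Merging within 1000 bp left 42.7% of H3K27ac and 40.3% of H3K4me2 elements in 1 subregion, and autosomes alone 40.4% of H3K4me2 elements. Counted unmerged, where a shared element counts once per list by construction, 21.1% of H3K27ac regions were in 1 subregion and 19.7% in all, and 19.95% and 19.2% of H3K4me2 regions. Without MEC, where all means 3 lists, the shares were 43.9% and 24.96% for H3K27ac and 38.1% and 29.6% for H3K4me2.

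With lists cut to their widest regions at the shortest length, 48.4% of H3K27ac elements were in 1 subregion and 12.1% in all, and 49.0% and 11.1% of H3K4me2 elements. Unique H3K27ac elements then numbered 2058 in ACC, 2095 in RSC, 2432 in LEC and 3994 in MEC, and unique H3K4me2 elements 2842 in ACC, 2694 in RSC, 2744 in LEC and 6816 in MEC. This setting leaves the MEC lists whole and removes the narrow regions of the others, so a rise in MEC-unique elements is built in. Doubly marked elements numbered 312 in ACC, 200 in RSC, 312 in LEC and 400 in MEC. Bases shared for H3K27ac were 40.5% for ACC and RSC, 39.1% for ACC and LEC, 19.6% for ACC and MEC, 33.8% for RSC and LEC, 25.8% for RSC and MEC and 21.03% for LEC and MEC. In the same order of pairs they were 40.1%, 41.5%, 10.998%, 38.2%, 15.1% and 13.7% for H3K4me2.

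In the widest 50% of each list, 44.2% of H3K27ac elements were in 1 subregion, and 43.1% of H3K4me2 elements, with 9.32% of the latter in all. Unique H3K27ac elements numbered 3355 in ACC, 2488 in RSC, 2420 in LEC and 1175 in MEC, and unique H3K4me2 elements 4022, 2428, 2614 and 2412 in this order. The lists are shorter by construction. Doubly marked elements numbered 219 in RSC, 305 in LEC and 93 in MEC. H3K27ac regions carried H3K4me2 in 58.6% of cases in ACC, 50.6% in RSC, 56.2% in LEC and 24.7% in MEC.

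In the full lists, 30.3% of H3K27ac elements were in 1 subregion and 19.7% in all, and 29.5% and 21.7% of H3K4me2 elements. MEC then had 1262 unique H3K27ac and 90 doubly marked elements. Bases shared, in the order of pairs given, were 52.8%, 54.1%, 25.7%, 48.3%, 33.9% and 29.4% for H3K27ac and 55.5%, 57.7%, 26.96%, 54.5%, 33.9% and 31.5% for H3K4me2. H3K4me2 was carried by 69.1% of H3K27ac regions in ACC, 64.5% in RSC, 70.3% in LEC and 62.2% in MEC.

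By the share of the shorter enhancer list overlapped, in the same order of pairs, the values were 67.0%, 68.1%, 61.9%, 55.5%, 67.0% and 56.2% for H3K27ac and 71.4%, 72.0%, 53.5%, 60.3%, 53.7% and 51.1% for H3K4me2.

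Random thinning to the shortest list removes regions of shared elements independently, which by construction raises uniqueness: 65.5% of H3K27ac elements were in 1 subregion and 1.44% in all, and 62.9% and 1.65% of H3K4me2 elements. Unique H3K27ac elements then numbered 5030 in ACC, 4719 in RSC, 4923 in LEC and 4704 in MEC, and doubly marked elements 505 in ACC, 428 in RSC, 545 in LEC and 503 in MEC. Absent from the full lists of both marks elsewhere were 3292 unique H3K27ac elements in ACC, 2920 in RSC, 2203 in LEC and 894 in MEC, 4244, 2199, 2989 and 2622 unique H3K4me2 elements in this order, and 69 doubly marked elements in MEC. The clustering ratio turned from below 1 to 1.15 in RSC and 1.20 in LEC within 20 kb, now past the threshold, and to 1.28 in ACC among doubly marked elements, or 1.29 on autosomes alone. Doubly marked elements of MEC gave 1.69 on autosomes alone, no longer past the threshold (permutation adjusted p = 0.119), against 2.37 on all chromosomes. For all unique elements of MEC the ratio turned to 0.9997 within 500 kb (permutation adjusted p = 0.974).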

Other observations

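The tests of RSC list length, of the RSC lead in H3K4me2, of width against uniqueness and of H3K4me2 over narrow unique regions were chosen after related results were seen. The tests of full lists and of MEC-unique elements were chosen before their results.

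H3K4me2-unique elements were carried most often by the H3K27ac list of their own subregion. In ACC it overlapped 37.4% (36.3 to 38.5) of them, against 22.0% for LEC and 21.9% for RSC. RSC-unique H3K4me2 elements carried RSC H3K27ac in 36.0% (34.7 to 37.4) and ACC H3K27ac in 28.9% (27.6 to 30.2). LEC-unique ones carried LEC H3K27ac in 30.3% (29.0 to 31.6) and ACC H3K27ac in 18.9% (17.8 to 20.1). MEC H3K27ac overlapped 12.6% (11.7 to 13.6) of RSC-unique H3K4me2 elements, more than the 5.84% (5.32 to 6.41) of ACC-unique and 5.27% (4.67 to 5.94) of LEC-unique ones. MEC-unique H3K4me2 elements carried little H3K27ac of any subregion, 9.14% (8.36 to 9.97) in MEC and 8.48% (7.74 to 9.30) in RSC.

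MEC H3K27ac regions were overlapped most often by the RSC list, although ACC had the longer list. With ACC, RSC and LEC thinned to 22973 regions each, RSC still led the higher of ACC and LEC by 7.27 percentage points (range over 100 draws 6.97 to 7.69). The higher was LEC, the shortest of these lists, which was left whole while RSC was cut. This argues against list length. In the full lists thinned to one length the lead was 6.21 points (6.07 to 6.37). Here RSC was the shortest and left whole, and thinning lowers the overlap of the other lists by construction. Unthinned, the full RSC list overlapped 82.97% of MEC regions, against 80.2% for ACC and 77.8% for LEC. RSC still led, which argues against the removal of regions from the enhancer lists. The thinned H3K4me2 lists also gave RSC a lead, of 3.39 points (3.24 to 3.57), but RSC was again the shortest list and left whole. Unthinned, the H3K4me2 enhancer lists gave 53.7% for RSC, 53.5% for ACC and 51.1% for LEC. The full H3K4me2 lists put ACC ahead, at 76.5% against 75.8% for RSC and 75.5% for LEC. A lead over ACC in H3K4me2 was thus seen only after thinning. Enhancer activity common to RSC and MEC and a preparation common to both would each predict a lead in H3K4me2. They cannot be told apart, since the labels give no batch.

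Of the MEC-unique H3K27ac elements, 1085 overlapped a full-list H3K27ac region of another subregion. In 99.7% (99.2 to 99.9) of these the widest region elsewhere was wider than the MEC element, with medians of 13725 and 1850 bp. Wider regions elsewhere left out of the enhancer lists stay open as an explanation, since every such region was left out by definition and the widest of 3 lists was taken, and so do different region boundaries in the MEC list. Of MEC regions inside excluded regions elsewhere, 16.9% (16.3 to 17.6) were kept as enhancers, -0.210 points from the 17.1% (16.4 to 17.9) in LEC, but above the 15.7% (14.997 to 16.4) in RSC and 12.1% (11.3 to 12.9) in ACC. A difference of the tissue was not tested.

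Unique regions were narrower than shared ones, and the narrowest 25% of the regions of each H3K27ac list were unique more often than the widest 25% by 16.3 (MEC) to 43.5 (ACC) percentage points, against 5.44 to 5.92 in shifted lists. This restates the pattern and leaves open whether narrow regions lie near the limit of detection. Borderline detection of elements equally present everywhere, if independent in the 2 marks, is argued against as the whole cause in RSC and LEC. In 2 of 2 the own H3K4me2 list overlapped more narrow unique regions than the longer ACC list with separate intervals (24.5% against 18.8% in RSC, 35.6% against 29.4% in LEC). In ACC the own list led by 7.14 points (6.28 to 8.10) after thinning to one length. Random thinning drops strong and weak regions alike, so it cannot take out what a longer list gains at weak regions. Borderline detection in ACC therefore stays open. A detection error common to both marks of a subregion would give the same lead and stays open. The labels describe only 2 input libraries per subregion for both marks. In MEC the own list lay -5.09 points from the RSC list, and the shorter MEC H3K4me2 list keeps this open.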
